A study of Rattus norvegicus with 24 samples.

How the data were processed

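RNA from normal distal colon and from colonic tumours was measured in 10 male (ACIxF344)F1-Pirc rats, which carry 1 mutant copy of the tumour suppressor Apc and form colonic tumours. Of these rats, 5 drank 4% dextran sodium sulfate (DSS, molecular weight 500000), an irritant of the colonic lining, from day 40 to day 47 and from day 54 to day 61. The other 5 were left untreated, and tissue was taken from all rats at day 97. Both tissues of each rat were measured, giving 20 samples of rat and tissue in 4 groups of 5 rats. There were 24 arrays, because 4 samples had a second array: the normal colon of rats 2, 3 and 6 and the tumour of rat 6. DSS rats were numbered 1, 5, 6, 7 and 9, and untreated rats 2, 3, 4, 8 and 10. The arrays came from 6 slides of 4 arrays, 3 scan days and 2 lots. Slides and lots were read from the slide identifiers and scan days from the file headers, since no label states them. Lot 1 held 3 rats and lot 2 held 2 rats of every group, and scan day 3 held the whole of lot 2.

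The authors labelled each sample with Cy3 and hybridized it together with a Cy5-labelled pool of colon RNA from wild-type rats to a 2-colour rat array; the dyes were not swapped. The deposited spot signals and backgrounds are in units of intensity, written by Feature Extraction 9.1.3.1 per the file headers. The deposited log ratio of each spot is log10 of Cy5 over Cy3 processed signal. It was recomputed within 0.01 for 73.5% to 97.5% of the spots of an array, and the remaining spots held a log ratio of 0. Partek is named in the submitters' processing notes with no stated role.

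All choices of test, filter, gene list, named gene and alternative in this paragraph and the 2 that follow it were made before the data were examined, except where stated. Log ratios were recomputed in R 4.3.3 with limma 3.58.1, statmod 1.5.0 and version 1.17.8 of data.table. Mean signals were corrected with normexp and an offset of 50, and log2 of Cy3 over Cy5 was normalized by loess within each array. Control spots and non-uniform spots had weight 0, and no normalization was applied between arrays. Spots of 1 probe were averaged without the non-uniform ones. A probe was kept when its Cy3 signal was well above background on at least 5 of the 24 arrays. Where several probes carried 1 symbol, the probe with the highest mean intensity stood for the gene. This gave 26170 features, of which 14079 carried a gene symbol, and 438 values (0.0697%) were missing. The array has 43379 gene spots and 41012 gene probes. A current gene was assigned to 22224 probes and 17124 genes: 15318 probes were named by accession, 4083 by a symbol that is still current and 2823 by an older name, and 18788 kept the name in the file. Of 540 members of the gene lists, 507 were on the array. No genome position was used, because the files give probe names and no genome build. For a probe well above background on no array of 1 group, the fold is given as a lower bound, and the same holds for a probe saturated on every array of the group with the higher value.

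Arrays of the same rat and tissue were averaged first, so that the rat was the replicate. limma fitted 1 model to the 20 samples with a mean per group, and its moderated tests were two-sided with Benjamini-Hochberg adjustment over all features and a threshold of 0.05. The model had 16 residual and 2.24 prior degrees of freedom. Comparisons were tumour against normal colon in untreated rats, in DSS rats and in both, DSS against untreated in each tissue, and the difference between the DSS effects in the 2 tissues, called the interaction. Errors after a log2 change are standard errors of that model, with 5 rats per group. The rat numbers were checked as animal numbers: after removal of group means, normal colon and tumour of 1 rat correlated across genes at 0.0802 to 0.566. Normal colon correlated best with its own tumour in 5 of the 10 rats. The median was 0.398 for the same rat, -0.202 for other rats of the same treatment and 0.297 for other rats of the same treatment and lot. Within a lot the same-rat values ran from -0.199 to 0.433. Rat was used as an alternative block, as planned.

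Lists of genes were tested with camera at a preset correlation of 0.01 between genes, adjusted over the 30 lists within each comparison, with an estimated correlation and with fry as alternatives. For each list the members past the threshold were also counted when adjusted over the list alone. Named genes followed a rule. In each comparison these were the 6 largest increases and 6 largest decreases past the threshold with a symbol, a usable signal and the same direction in every rat. From each list that passed, or that had at least 3 members past the threshold, the 3 members with the smallest p were added. Apc, Axin2, Lgr5, Mmp7, Ptgs2, Il1b, Reg3b, Lcn2, Car1, Slc26a3 and Muc2 were always eligible. Where fewer than 12 genes passed, the 5 genes with symbols and the smallest p in each direction were given as values. The text names a subset of these genes, chosen after their values were seen, and other genes are named as chosen afterwards. Of the genes left out, 2 were left out for reasons other than their values.

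The limma fit and its threshold were tested on simulated log ratios of 26170 genes, of which 200 changed, with independent noise at the spread measured in these rats. Background correction, loess, the signal filter and the averaging of arrays were not simulated. Nor were the correlation within a rat and the differences between lots, so the recovery leaves out their effects. A log2 change of 1 was recovered for 80.6% of changed genes between tumour and normal colon of untreated rats and for 73.1% of DSS rats. The recovery at that size was 71.6% for DSS in normal colon, 74.6% for DSS in tumours, 65.7% for the interaction and 88.1% for both treatments together. At a log2 change of 0.5 the recovery was, in the same order, 41.8%, 38.8%, 31.3%, 43.3%, 22.4% and 70.2%. At 2 it was 97.0%, 100%, 92.4%, 98.5%, 92.4% and 98.5%. Unchanged genes called numbered 11, 10, 5, 6, 6 and 4.

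The alternatives were a normexp offset of 10, the deposited log ratio, median centring without loess, Aquantile between arrays, and the sample channel alone. Others were no filter, a filter of 20 of 24 arrays, the mean of all probes of a gene, the first array only, all 24 arrays with the sample as random block, and rat as fixed or random block. The rest were slide, scan day or lot as fixed block, each lot alone, only the 2 groups compared, array weights, a variance prior with trend and robust fitting, a fold of at least 2, and leaving out each rat in turn. Leaving out the 3 arrays with raised signal, each scan day of lot 1 alone, and the squamous list mean as a covariate were chosen after seeing the data. Under the alternatives, lists were tested with camera on z-scores of limma's moderated statistics. Untransformed statistics had been used first, and were replaced after those results were seen, because they gave other calls for ratios that had not changed. The members of a skeletal muscle list above background were first counted over tumour arrays, and over all arrays of each rat after that result was seen, as its test had been written. The test of slide, scan day or lot was widened to counts within lots after these were seen, and leaves out scan days, where some groups held 1 rat. The test of squamous cells first counted members of the squamous list itself, and was replaced afterwards by 20 other squamous genes measured here. With z-scores, 1 of the 180 list calls differed from camera on the data. Among 3445 genes with several probes, probes of 4 genes were called in both directions between tumour and normal colon of untreated rats, and of 2 genes over both treatments. The Cy5 channel alone, array features other than gene spots and the submitters' own summary values were not analysed.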

Results

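The data comprised 24 2-colour arrays of colon from 10 Pirc rats, read as log2 of the sample over a common pool of wild-type rat colon. Each of the 4 groups held 5 rats: normal colon of untreated rats (7 arrays), normal colon of DSS rats (6 arrays), tumours of untreated rats (5 arrays) and tumours of DSS rats (6 arrays). On 21 arrays, 47.6% to 70.5% of the probes were well above background in the sample channel. On the other 3, the first array of rat 2 normal colon, rat 4 normal colon and rat 9 tumour, the share was 86.9% to 95.2%, and the negative controls had median intensities of 57.8 to 120 against 38.7 to 63.1 elsewhere. Second arrays correlated across genes with the first at 0.813 for rat 2 normal colon and at 0.953 to 0.968 for the other 3 samples. Between rats of 1 group the median correlation across genes was 0.851 to 0.916 within a lot and 0.625 to 0.776 across lots, where genes are not independent replicates. The arrays of lot 2 had 388 to 452 saturated Cy5 probes, against 29 to 152 on those of lot 1. Lot 2 is also scan day 3, so the 2 cannot be told apart. The normal colon of DSS rats 1 and 5 correlated across genes at 0.970, above the second arrays of 1 sample. The number of rats, 5 per group, limited the precision.

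The comparison of tumours with normal colon in untreated rats shows the tumour profile without the irritant. Mmp7, a matrix metalloprotease of intestinal tumours, rose by 5.56 ± 0.33 on the log2 scale (47.0-fold, adjusted p = 1.76e-08, n = 5 rats per group). Cd44, an adhesion receptor and Wnt target, rose by 4.65 ± 0.25 (adjusted p = 6.74e-09), and by 1.07 on its other probe. Arg1 and Ass1, enzymes of arginine metabolism, rose 23.4-fold and 19.8-fold. The Paneth cell defensin Defa6 rose by 4.70 ± 0.39 (26.0-fold). Slc26a3, the chloride and bicarbonate exchanger of absorptive colonocytes, changed by -4.54 ± 0.73 (23.2-fold lower, adjusted p = 0.000348), and Cmahp changed by -4.95 ± 0.32 (31.0-fold lower). Each of these genes moved the same way in 5 of 5 rats, which the rule required of the largest changes.

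Of 11 measured goblet and secretory genes, 9 fell, 0 rose and 2 did not pass in these tumours, against 11 that fell when adjusted over the list alone (list median -1.68, adjusted p = 6.16e-09 in camera and 0.0737 with an estimated correlation). Among them were Tff3, a trefoil peptide secreted with mucin, at -2.26 ± 0.30, and the goblet cell transcription factor Spdef at -2.17 ± 0.33. The mucin Muc2 had -0.92 ± 0.32 and did not pass (adjusted p = 0.0548), but it passed with lot as block (0.00115) and with rat as a fixed block (0.00383). Of 25 absorptive colonocyte genes, 14 fell, 3 rose and 8 did not pass, and 16 fell and 3 rose when adjusted over the list alone (median -1.29, adjusted p = 2.39e-07, and 0.154 with an estimated correlation). The water channel Aqp8 changed by -2.13 ± 0.32 and the mineralocorticoid receptor Nr3c2 by -2.09 ± 0.30. Of 13 enteroendocrine genes, 9 fell and 1 rose, in both counts, with the peptide hormone Pyy at -2.46 ± 0.31 (adjusted p = 6.59e-06, and 0.154 with an estimated correlation).

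Of 26 Wnt pathway targets, 11 rose, 1 fell and 14 did not pass, and 13 rose and 1 fell when adjusted over the list alone (median 0.35, adjusted p = 5.63e-07, and 0.0643 with an estimated correlation). The secreted Wnt inhibitor Wif1 rose by 3.03 ± 0.34, Myc by 1.71 ± 0.29 and the feedback gene Axin2 1.99-fold (adjusted p = 0.00734). The stem cell receptor Lgr5 had 0.19 (adjusted p = 0.622) and Apc -0.28 (adjusted p = 0.157), and neither passed. Of 17 matrix proteases and inhibitors, 8 rose and 9 did not pass, with 12 over the list alone (adjusted p = 6.16e-09, and 0.0643 with an estimated correlation). Of 19 regenerative and fetal-like epithelium genes, 13 rose and 6 did not pass, with 14 up and 1 down over the list alone (median 1.08, adjusted p = 1.08e-08, and 0.0643 with an estimated correlation). Of 19 ribosome biogenesis genes, 9 rose and 0 fell, with 12 over the list alone (adjusted p = 1.51e-07, and 0.154 with an estimated correlation).

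Of 30 cytokines and chemokines, 14 rose, 2 fell and 14 did not pass, with 17 up and 3 down over the list alone (median 0.55, adjusted p = 2.58e-06, and 0.142 with an estimated correlation). The neutrophil attractant Cxcl3 rose by 2.83 ± 0.33 and Il1b by 2.14 ± 0.30. Of 12 neutrophil genes, 7 rose and 5 did not pass, with 9 up and 1 down over the list alone (list adjusted p = 1.68e-06, and 0.102 with an estimated correlation). The calprotectin genes S100a8, read from the brightest of its 3 probes, and S100a9 rose by 3.62 ± 0.39 and 3.90 ± 0.39. Of 13 macrophage genes, 9 rose, 10 over the list alone (adjusted p = 6.59e-06, and 0.178 with an estimated correlation). Of 20 fibroblast and matrix genes, 9 rose, 10 over the list alone, with the proteoglycan Dcn at 3.03 ± 0.44 (adjusted p = 4.15e-06, and 0.268 with an estimated correlation). Squamous epithelium genes gave 1 higher of 11 with a list median of -0.08, a mean of 0.18 and an adjusted p of 0.760, so that median and mean differed in sign. Reg3b, an antimicrobial lectin, had 1.44 ± 1.11 and did not pass. Nor did Lcn2 at 0.09, above background on 5 of 7 normal and 4 of 5 tumour arrays with ratios near 0 in every group.

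In limma, 4709 of 26170 features passed, 2249 higher and 2460 lower. The count was 6580 with lot as block, 3184 within lot 1 and 2407 within lot 2, 900 with median centring in place of loess, 4263 without the 3 arrays with raised signal, and 2600 without rat 8. The list medians within lots 1 and 2 were -1.32 and -2.20 for goblet genes, -0.91 and -1.55 for absorptive genes, 0.30 and 0.39 for Wnt targets, 1.06 and 1.29 for regenerative genes, 0.41 and 1.01 for cytokines and chemokines, 0.41 and 1.35 for macrophage genes, and 0.46 and 0.86 for fibroblast and matrix genes.

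**Figure D1:**
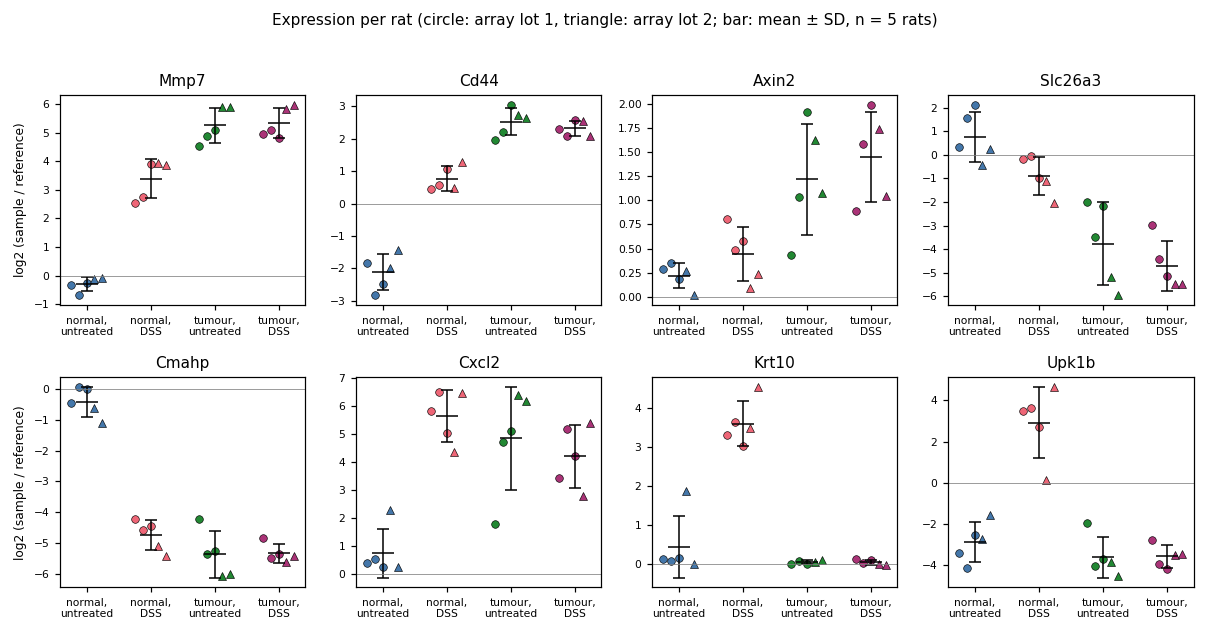
Log2 ratio of sample to reference pool for 8 genes in the 4 groups, with circles for rats of lot 1, triangles for rats of lot 2, and bars for the group mean with its SD (5 rats per group). Mmp7, Cxcl2, Krt10 and Upk1b stood higher in normal colon of DSS rats than in normal colon of untreated rats, while Axin2 differed between those groups by 0.22 ± 0.24.

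In DSS rats, tumours are compared with the normal colon of animals that had drunk the irritant. Genes named as largest changes were required to move the same way in all 5 rats. Upk1b, a uroplakin of the urothelium, changed by -6.52 ± 0.67 (adjusted p = 8.89e-06, well above background on 3 of 6 tumour arrays), Krtdap, a protein of differentiating keratinocytes, by -5.15 ± 0.61 (well above background on 1 of 6 tumour arrays), Slurp1, a protein secreted by keratinocytes, by -5.00 ± 0.34 (31.9-fold lower), and the protease inhibitor Csta by -5.06 ± 0.76, each in 5 of 5 rats. The membrane protein Tm4sf1 rose by 3.21 ± 0.47 (9.28-fold), Armh4 by 3.87 ± 0.42 (14.7-fold, adjusted p = 1.42e-05) and Mmp7 by 1.95 ± 0.33 (3.85-fold, adjusted p = 0.00104).

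Of 11 squamous epithelium genes, 8 were lower in tumours and 3 did not pass, and 11 were lower when adjusted over the list alone (median -2.47, adjusted p = 1.27e-18, and 0.0173 with an estimated correlation). The list mean was 0.34 in tumours of DSS rats, 0.26 in normal colon of untreated rats and 2.54 in normal colon of DSS rats. The difference thus came from high values in the normal colon of DSS rats. The keratins Krt10 and Krt5 changed by -3.57 ± 0.29 and -2.65 ± 0.21, and were well above background on 1 and 2 of 6 tumour arrays. Of 11 goblet genes, 8 fell in both counts, with Tff3 at -2.39 ± 0.30 and the goblet cell protein Clca1 at -3.29 ± 0.56 (list adjusted p = 1.97e-09, and 0.0658 with an estimated correlation). Of 25 absorptive genes, 12 fell and 1 rose, with 17 down and 2 up over the list alone, and Slc26a3 changed by -3.83 ± 0.73 (list median -1.18, adjusted p = 0.176 with an estimated correlation). Of 26 Wnt targets, 14 rose, 1 fell and 11 did not pass, with 17 up and 1 down over the list alone (median 0.54, adjusted p = 1.97e-09, and 0.0173 with an estimated correlation). Wif1 rose by 2.39 ± 0.34, Ccnd1, a cyclin of the cell cycle, by 0.98 ± 0.12, and the Wnt inhibitor Nkd1 by 1.28 ± 0.16. Axin2 rose by 1.01 ± 0.24 (adjusted p = 0.0134), and did not pass without rat 5 (adjusted p = 0.0644), rat 6 (0.053) or rat 7 (0.0776). Of 15 antimicrobial genes, 5 fell and 1 rose, with 6 down and 1 up over the list alone, among them Defb1, an epithelial defensin, at -3.47 ± 0.35, above background on 1 of 6 tumour arrays (list adjusted p = 0.00164, and 0.0173 with an estimated correlation). Of 30 cytokines and chemokines, 3 rose and 3 fell, and the list did not pass (adjusted p = 0.231). Il1b had -0.33 ± 0.30 (adjusted p = 0.6). Regenerative genes, 1 higher and 3 lower of 19, had an adjusted p of 0.994.

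In limma, 2002 features (7.65%) passed, 987 higher and 1015 lower. Of these, 527 also rose and 445 also fell in tumours of untreated rats, against 84.8 and 95.4 with independent calls, and 43 and 9 went the opposite way. Of the 1015 lower features, 396 were higher with DSS in normal colon, among them Upk1b, Csta, Krt10, Krt5 and Defb1. The normal colon of DSS rats enters both comparisons with opposite sign, so part of this overlap is built in. The count was 3273 with rat as a fixed block, 3377 as a random block, 3200 with lot as block, 2026 within lot 1, 112 within lot 2, 643 with median centring, 1488 without the 3 arrays with raised signal, 1184 without rat 1, 1095 without rat 5 and 1206 without rat 9. Within lots 1 and 2 the list medians were -1.97 and -2.98 for squamous genes, -1.41 and -1.13 for goblet genes, and 0.39 and 0.74 for Wnt targets. Over all 10 rats, 5448 features passed, 2795 higher and 2653 lower, with Mmp7 up by 3.75 ± 0.23 (13.5-fold, 10 of 10 rats), Slc26a3 at -4.18 ± 0.52, and 14 of 26 Wnt targets higher (adjusted p = 2.84e-09, and 0.0480 with an estimated correlation).

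The comparison of DSS with untreated rats in normal colon asks whether the irritant altered colonic expression at day 97, after its last use at day 61. Upk1b rose by 5.82 ± 0.67 (56.3-fold, adjusted p = 3.82e-05), the epidermal fatty acid carrier Fabp5 by 5.29 ± 0.43 (39.0-fold, adjusted p = 1.74e-06), and the neutrophil attractants Cxcl2 and Cxcl1 by 4.88 ± 0.74 (29.4-fold) and 4.25 ± 0.56 (19.0-fold). Mmp7 rose by 3.69 ± 0.33 (12.9-fold, adjusted p = 3.61e-06) and Cd44 by 2.89 ± 0.25 (7.39-fold), while the other Cd44 probe had 0.39 and did not pass (adjusted p = 0.298). Cmahp changed by -4.33 ± 0.32 (20.1-fold lower), the retinoic acid enzyme Aldh1a1 by -2.94 ± 0.44 (7.68-fold lower), and the gluconeogenic enzyme Pck1 by -2.08 ± 0.47. For Upk1b, Fabp5, Cxcl2, Cmahp, Aldh1a1 and Pck1 the 5 values of 1 treatment all lay above the 5 of the other. The rule for the largest changes required this, so it adds no support.

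All 11 squamous epithelium genes rose, in both counts (median 2.53, adjusted p = 1.82e-19, and 0.0365 with an estimated correlation), with Krt10 at 3.17 ± 0.29 (above background on 3 of 7 untreated arrays) and Krt5 at 2.53 ± 0.21. All 11 were counted as above background in normal colon of DSS rats, against 7 in that of untreated rats, so the signal filter favoured a rise. The mean of the list per rat was 2.11 to 3.60 in DSS rats, 1.17 in untreated rat 8 and at most 0.07 in the other untreated rats. Of 19 regenerative genes, 7 rose and 12 did not pass, with 9 over the list alone (median 0.85, adjusted p = 7.86e-09, and 0.0851 with an estimated correlation). Anxa1, an annexin, rose by 1.66 ± 0.20. Of 17 matrix proteases and inhibitors, 5 rose in both counts, with the plasminogen activator Plat at 2.36 ± 0.26 (list adjusted p = 1.57e-07, and 0.108 with an estimated correlation). Of 30 cytokines and chemokines, 9 rose and 1 fell, with 10 up and 1 down over the list alone (median 0.28, adjusted p = 0.112 with an estimated correlation), and Il1b rose by 2.08 ± 0.30. Of 12 neutrophil genes, 3 rose, with 6 up and 1 down over the list alone, and S100a8 rose by 3.15 ± 0.39 (list adjusted p = 3.11e-06, and 0.112 with an estimated correlation). Other S100a8 probes had 0.76 (adjusted p = 0.0796) and 0.95 (0.0412). Of 24 proliferation genes, 5 rose and 19 did not pass, with 8 over the list alone, among them the ribonucleotide reductase subunit Rrm2 at 1.26 ± 0.25 (list adjusted p = 1.57e-07, and 0.303 with an estimated correlation). Of 25 absorptive genes, 3 fell and 22 did not pass, with 3 down and 1 up over the list alone (adjusted p = 0.0265, and 0.495 with an estimated correlation; 0.0535 without rat 6, 0.0581 without rat 10). Slc26a3 had -1.64 ± 0.73 and did not pass (adjusted p = 0.203), but it passed with lot as block (0.0274). Axin2 had 0.22 ± 0.24 (adjusted p = 0.662). Wnt targets gave 3 higher and 1 lower of 26 (median 0.08, adjusted p = 0.0510).

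In limma, 1905 features (7.28%) passed, 1026 higher and 879 lower. Of the 1026, 507 also rose in tumours of untreated rats, and of the 879, 608 also fell there, with 8 and 5 in the opposite direction. Both comparisons share the untreated normal colon, which by construction gave a correlation across genes of 0.502 in simulated groups without change, against 0.647 here. The covariance, which is not fixed in this way, was 0.0186 in the simulated groups and 0.134 here. The count was 3483 with lot as block, 3091 within lot 1 and 2 within lot 2, and it was highest with array weights, as given below. With median centring it was 361, most of them higher. It was 1281 without the 3 arrays with raised signal, 1187 without rat 3, 1248 without rat 5, and 0 with the squamous list mean as a covariate (limma, 3529 at an unadjusted p under 0.05). DSS rats 1 and 5, whose normal colon correlated at 0.970, lie in lot 1. If they were 1 animal, the count within lot 1 would rest on an understated spread. Within lots 1 and 2 the list medians were 2.23 and 2.605 for squamous genes, 0.68 and 0.59 for regenerative genes, and 0.53 and 0.22 for cytokines and chemokines.

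**Figure D2:**
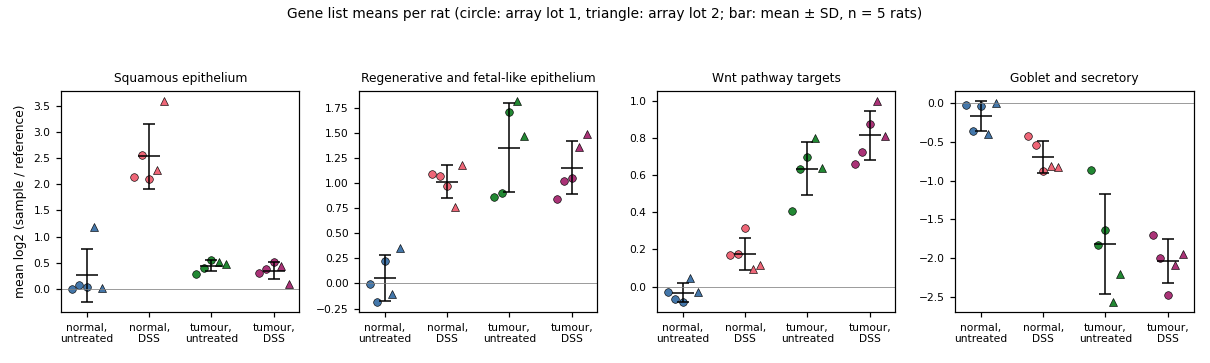
Mean log2 ratio to the reference pool over the squamous, regenerative, Wnt and goblet lists, per rat in the 4 groups, with circles for lot 1, triangles for lot 2, and bars for the group mean with its SD. The squamous mean lay between 2.11 and 3.60 in normal colon of DSS rats, at 1.17 in untreated rat 8, and at or below 0.55 in the tumours.

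The comparison of DSS with untreated rats in tumours asks whether the irritant altered tumour expression. No gene passed in limma (0 of 26170, smallest adjusted p 0.164), and 1657 features had an unadjusted p under 0.05, which is 6.33% of those tested. The tumour values were -0.88 ± 0.16 for Alas1, the first enzyme of haem synthesis (adjusted p = 0.164), -0.72 ± 0.14 for Rac2, a GTPase of blood cells (0.194), 0.66 ± 0.12 for Ptov1 (0.164) and 0.80 ± 0.16 for the endodermal transcription factor Foxa3 (0.2). Mmp7 had 0.08 ± 0.33, Axin2 0.23 ± 0.24, Slc26a3 -0.94 ± 0.73 and Il1b -0.39 ± 0.30, each with an adjusted p of 1 and 5 rats per group. The 95% interval of the change excluded a 2-fold change for 24798 features (94.8%), among them 1696 of the 1905 that passed in normal colon. These ratios carry the offset of 50, which shrinks the change of a dim probe. For dim probes the interval therefore does not exclude a 2-fold change of the transcript.

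At the level of lists, 10 of 30 passed in camera without any member past the threshold over all genes, and 1 of the 10 passed with an estimated correlation. Of 15 antimicrobial genes, 0 passed (median -0.57, adjusted p = 0.000129, and 0.00649 with an estimated correlation). Proliferation genes had a median of 0.28 (adjusted p = 1.09e-05, and 0.594 with an estimated correlation), Wnt targets 0.14 (0.00152, and 0.454 with an estimated correlation; 0.0962 without rat 2) and neutrophil genes -0.21 (0.000133, and 0.454 with an estimated correlation). Adjusted over the list alone, 3 Wnt targets were higher, Nkd1 (0.66), Ephb3 (0.74) and Ephb4 (0.68), and Clca4 (-1.30), Ms4a12 (-0.75), Tff3 (-1.03) and Ly6al (-0.93) of the absorptive, goblet and regenerative lists were lower. These 7 genes lie outside the rule for named genes and were chosen after their values were seen.

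The count of 0 stayed 0 with lot as block and within each lot, and was 11 with slide as block, 50 with scan day as block, 603 within scan day 1 (1 untreated tumour, and 3228 in normal colon there), 1 with the deposited log ratio and 3 without rat 2. Within lots 1 and 2 the list medians were -0.34 and -0.58 for antimicrobial genes, 0.13 and 0.51 for proliferation genes, and 0.07 and -0.61 for cytokines and chemokines.

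The interaction tests whether the effect of DSS differed between tumour and normal colon. It was negative for genes that rose with DSS in normal colon, -5.24 ± 0.61 for Fabp5 (37.7-fold, adjusted p = 0.000226), -7.28 ± 1.18 for Clca4l (155-fold, adjusted p = 0.00209), -5.78 ± 0.95 for Upk1b, -5.52 ± 1.05 for Cxcl2 and -3.61 ± 0.46 for Mmp7 (12.2-fold, adjusted p = 0.000421). It was -4.36 ± 0.55 for S100a8 on the brightest of its 3 probes, of which the others rose less with DSS in normal colon. It was -3.17 ± 0.42 for Krt10 and -2.47 ± 0.42 for Il1b (adjusted p = 0.00326), and the tumour part for Krt10 was near background (above it on 1 of 5 untreated and 1 of 6 DSS arrays). It was positive for genes that fell in normal colon, 4.36 ± 0.45 for Cmahp (20.6-fold, adjusted p = 0.000154) and 2.88 ± 0.44 for the carboxylesterase Ces1e. Axin2 had 0.01 (adjusted p = 0.994) with 5 rats per group.

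Of 11 squamous genes, 7 had a negative interaction and 4 did not pass, with 10 over the list alone (median -2.599, adjusted p = 8.56e-18, and 0.0263 with an estimated correlation). For 19 regenerative genes the counts were 5 and 14, with 8 over the list alone (median -1.05, adjusted p = 4.80e-10, and 0.0358 with an estimated correlation). For 15 antimicrobial genes they were 3 and 12, with 4 over the list alone (median -0.87, adjusted p = 2.47e-05, and 0.00503 with an estimated correlation), with Defb1 at -3.13 ± 0.49. For 30 cytokines and chemokines they were 7 and 23, with 9 over the list alone (adjusted p = 0.0683 with an estimated correlation), for 12 neutrophil genes 3 and 9, with 7 over the list alone (0.0612 with an estimated correlation), and for 17 proteases and inhibitors 2 and 15, with 7 over the list alone (0.0887 with an estimated correlation). Wnt targets gave 1 positive and 1 negative of 26 (median 0.04, adjusted p = 0.973). Defb1 was above background on 1 of 5 untreated and 1 of 6 DSS tumour arrays, so its interaction rests on normal colon.

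In limma, 666 features (2.54%) passed, 224 positive and 442 negative. The interaction contains the DSS effect in normal colon with the opposite sign, so the overlap with the genes called there is built in. The count was 1480 with rat as a fixed block and 1649 as a random block, 1365 with lot as block, 416 within lot 1 and 3 within lot 2, 185 with median centring, 315 without the 3 arrays with raised signal, and 322, 428, 344, 385, 371 and 387 without rats 1, 3, 4, 5, 8 and 9. Within lots 1 and 2 the list medians were -2.29 and -2.66 for squamous genes and -1.12 and -0.93 for regenerative genes.

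**Figure D3:**
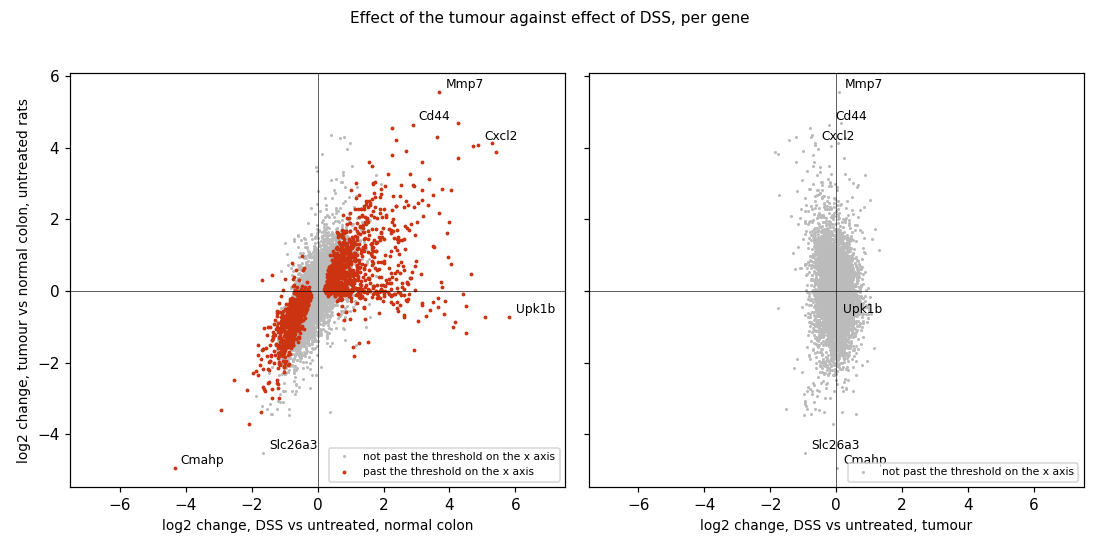
Log2 change of each gene in tumours of untreated rats against normal colon (vertical axis), plotted against its log2 change with DSS in normal colon (left) and in tumours (right), with genes past the threshold on the horizontal axis in red. There were 1905 red genes on the left and 0 on the right. The 2 effects on the left share the untreated normal colon and correlated across genes at 0.647 (covariance 0.134). In simulated groups without change, sharing by construction gave 0.502 (covariance 0.0186).

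**Figure D4:**
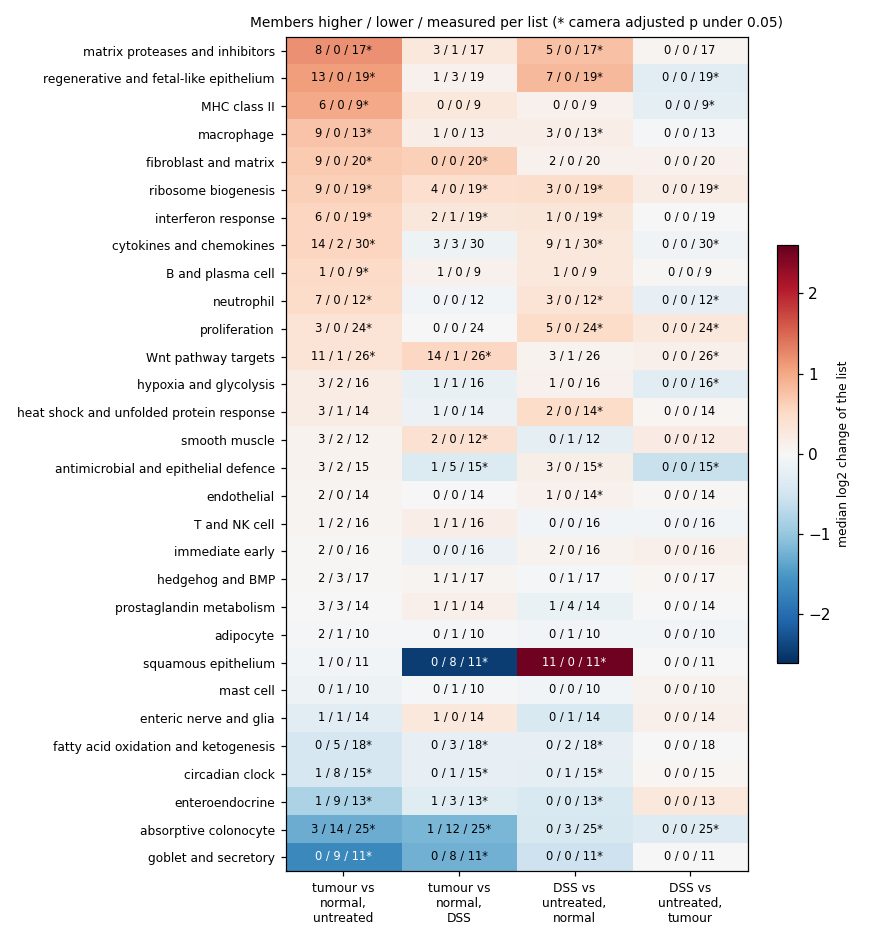
Median log2 change of each gene list in 4 comparisons as colour, with the numbers of members higher, lower and measured in each cell and a star where camera gave an adjusted p under 0.05. Squamous genes had a median of 2.53 with DSS in normal colon and of -2.47 between tumour and normal colon of DSS rats.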

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

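The tests of array lot, of slide, scan day or lot, and of tumour tissue on genes higher in tumours were chosen after the result was seen, as were the test of squamous cells (its gene list was drawn up before its own values were seen), the covariate and the genes examined for a rat far from its group.

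The effect of DSS differed between tumour and normal colon in limma's interaction for 666 genes. For lists the median difference was -2.599 for squamous genes, -1.05 for regenerative, -0.87 for antimicrobial, -0.83 for proteases and inhibitors, -0.54 for neutrophil, -0.43 for MHC class II, -0.38 for macrophage, -0.35 for cytokines and chemokines and -0.34 for hypoxia and glycolysis genes. It was 0.64 for smooth muscle, 0.52 for enteroendocrine and 0.22 for circadian genes, with 0.25 and 0.97 for smooth muscle and 0.18 and 1.14 for enteroendocrine genes within lots 1 and 2. With an estimated correlation 9 of these 12 lists no longer passed, and the squamous (adjusted p = 0.0263), regenerative (0.0358) and antimicrobial (0.00503) lists did. Among named genes it was -7.28 for Clca4l, -5.78 for Upk1b, -5.53 for Csta, -5.52 for Cxcl2, -5.24 for Fabp5 and -5.22 for Alpl. It was -4.36 for S100a8 (the brightest of 3 probes), -3.69 for S100a9, -3.61 for Mmp7 and -3.60 for Cxcl3. It was -3.17 for Krt10, -3.13 for Defb1, -2.63 for Plat, -2.55 for Krt5 and -2.47 for Il1b. It was 4.36 for Cmahp, 2.88 for Ces1e, 2.20 for Anpep (0.19 on its other probe, adjusted p = 0.645) and 2.14 for Pdlim3. In tumours, Krt10 and Defb1 were well above background on 1 of 5 untreated and 1 of 6 DSS arrays, so their difference rests on normal colon, and Alpl was above it on 1 of 7 arrays of untreated normal colon. Speg had 2.21 (adjusted p = 0.0586 without rat 4, 0.0567 without rat 8, 0.0616 without rat 9). Sstr1 had 2.22 (adjusted p = 0.0332; without rats 1, 3, 4, 5, 7, 8, 9 and 10 it was 0.0909, 0.0562, 0.0843, 0.0624, 0.0585, 0.11, 0.0625 and 0.0666).

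Over 99 genes drawn from the rule for named genes, 26 of 396 combinations of gene and group (6.57%) had 1 rat far from the other 4, where chance gives about 1 in 20. Of these, 12 were in the normal colon of untreated rat 8, with the other 4 rats between -0.61 and 0.81: Stfa3 4.65, Csta 4.44, Krtdap 4.21, Cxcl2 2.30, Krt10 1.86, S100a9 1.82, Slurp1 1.55, Clca4l 1.39, Defb1 1.23, Cxcl1 1.06, Krt5 0.70 and Calml3 0.59. In normal colon of DSS rat 9, Csta had 7.73, Car4 -1.77 and Prss23 -1.86. In that of DSS rat 6, Bop1 had 0.96 and Ces1e -2.25. In untreated normal colon, Anpep had -0.50 in rat 4, C10h16orf89 -0.25 in rat 3 and Hadh -0.026 in rat 2. In tumours, Klf4 had 0.22 in rat 2, Pdlim3 -1.70 in rat 4, Dmbt1 -3.17 in rat 1, Dstn -0.83 in rat 7, and Tlr2 2.40 and Apc -0.59 in rat 9.

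The squamous genes were higher in normal colon of DSS rats. Every group held 3 rats of lot 1 and 2 of lot 2, so a shift by array lot alone could not raise 1 group. The list median was 2.23 in the lot where it was smaller, so the rise was present in both lots. The tables argue only weakly against reach into the anal sphincter. There, 13 skeletal muscle genes had a median of -0.0398 and a mean of -0.16 (SD 0.38) where a rise of 1 was predicted. Of them 6 were above background in every rat, the smallest count that the test accepts. With the first count, over tumour arrays, the test had been undecided. Squamous cells in the pieces remain a candidate explanation. A list of 20 other measured squamous genes, not looked at before, had a median of 1.31 with 15 higher and 0 lower (camera p = 5.42e-23, and 0.000781 with an estimated correlation). In tumours of untreated rats, 5 of the 20 were also higher and 1 was lower (median 0.027), so not every member is particular to normal colon of DSS rats. All 20 were counted as above background in normal colon of DSS rats, against 12 in that of untreated rats. A gene could thus pass the signal filter through the DSS rats alone, which favours a rise. The list mean of 1.17 in untreated rat 8 goes with squamous cells. Whether squamous cells grew into the colon after DSS or lay at its margin was not tested.

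Changes of tumours were also present in normal colon of DSS rats. Shared untreated samples could not be the whole cause, since splitting them between the comparisons left a correlation across genes of at least 0.374. Tumour tissue in these pieces may contribute to the decreases, but the test cannot tell it from any other even dilution of normal colon. The share each of 90 genes needs had a median of 0.609 and an interquartile range of 0.199996, at the bound of 0.2 set beforehand. That range was at least 0.229 in each rat alone, and 13 genes need over 0.8 and 4 under 0.2. The 104 increases argue against tumour tissue as the whole cause, with a range of 0.602. However, the share is bounded above for decreases and not for increases, of which 20 need over 1, so the ranges differ in scale. In addition, 11 Wnt targets had a median change of 0.20 where the median share of the decreases would give 0.86. An effect of DSS on the colon itself stays open, and the covariate did not decide it: Mmp7 went from 3.69 ± 0.30 to 3.11 ± 0.74, Cmahp from -4.33 ± 0.28 to -3.34 ± 0.62, Fabp5 from 5.29 ± 0.48 to 2.62 ± 0.77, Cxcl1 from 4.25 ± 0.35 to 2.75 ± 0.72 and Defa6 from 4.25 ± 0.34 to 4.79 ± 0.86, and their calls ended as the changes of all but Defa6 shrank and the median standard error rose from 0.11998 to 0.274, since treatment explains 83.4% of the variance of the squamous mean.

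No gene passed between the tumours of DSS and untreated rats in limma, with 1657 at an unadjusted p under 0.05. A larger spread between tumours could not alone account for this, since 32 genes changed by at least 2-fold at any p, against 692 in normal colon. Slide, scan day or lot as block gave at most 50 genes, against 4021 in normal colon with scan day as block, which argues against these as the whole cause; the 603 within scan day 1, against 3228, rest on 1 untreated tumour and decide nothing. A smaller effect of DSS on tumours than on normal colon goes with the 666 genes of the interaction, and remains a hypothesis from the same data. The intervals that exclude a 2-fold change for 24798 genes were counted in tumours alone, so they do not compare the tissues. They also hold only for ratios with the offset, which shrinks changes of dim genes.

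Other splits of the samples were counted. Chance alone was unlikely for DSS in normal colon (1 of 100 splits gave as many, 1905 genes, highest other 459). The same held for the interaction (1 of 100, 666 genes, highest other 1). It also held for both treatments together (1 of 100, 5448 genes, highest other 1593). The real split was among the 100, so 1 of 100 is the smallest share possible and chance is not excluded. The splits also treat all rats as separate animals. That fails if the most alike pair of arrays, both normal colon of DSS rats, came from 1 animal. For DSS in tumours the real count was 0, so all 100 splits gave at least as many by construction and say nothing about chance. The highest there, 165 genes, came from a split with all rats of lot 2 on 1 side, which points to a structure of the tumours by lot; with lot as block the real count was 0. Between tumour and normal colon there were 16 splits, too few for a share under 0.05, with 4709 genes and 854 in the highest other for untreated rats, and 2002 and 11 for DSS rats.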

How the results depend on the processing

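Of the settings here, leaving out the 3 arrays with raised signal, each scan day of lot 1 alone and the squamous list mean as a covariate were chosen after the results were seen. Among 373 changes of named genes, 80 kept their direction and side of the threshold under every setting run, and among 180 list tests 21 did. Over all settings, single genes gave 11452 values with the same call, 972 that lost it, 59 that gained it and 5 that turned, and lists gave 5726, 356, 257 and 21. Aquantile leaves log ratios unchanged, so it changed no gene. The circadian list in the interaction, on the threshold, had an adjusted p of 0.0482 in camera and 0.0516 in camera on z-scores under Aquantile. That shift came from the change of test and not from Aquantile. Where no cause is named, the cause was not tested. Rat as a fixed block was not run for DSS against untreated, because treatment does not vary within a rat.

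In the order tumour against normal colon of untreated rats, of DSS rats, DSS in normal colon, DSS in tumours, interaction and both treatments, the reference counts were 4709, 2002, 1905, 0, 666 and 5448. Median centring without loess gave 900, 643, 361, 185 for the interaction and 1439 for both treatments, and left 0 in tumours. It made 60.2% of the calls in DSS tumours and 81.4% in DSS normal colon higher, against 49.3% and 53.9%. It moved the median of all genes, in the same order, to -0.0526, 0.251, -0.0985, 0.225, 0.381 and 0.0437, and the sample channel alone moved it to -0.215, 0.179, -0.308, 0.0779, 0.348 and 0.0253. The deposited log ratio gave 1 gene in tumours and 1234 in the interaction.

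Rat as a fixed or random block, a paired design, gave 3273 and 3377 for tumours of DSS rats and 1480 and 1649 for the interaction, and moved no other count by more than 1.5 times. Slide as block gave 3185 for tumours of DSS rats, 3632 for DSS in normal colon, 11 for DSS in tumours and 1183 for the interaction. Scan day as block gave 3433, 4021, 50 and 1553, and lot as block 3200, 3483, 0 and 1365. Array weights gave 3531, 5419, 0 and 1287. The highest weights fell on the normal colon of DSS rats 5 (2.59) and 1 (2.48), which may be 1 animal. The 5419 for DSS in normal colon would then rest on an understated spread. A fold of at least 2, which can only remove genes, left 1337, 703, 575, 461 for the interaction and 851 for both treatments.

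Within lot 1 the count was 3091 for DSS in normal colon and 416 for the interaction. Within lot 2, with 2 rats per group, it was 2407, 112, 2, 0, 3 and 2525 in the same order. Within scan day 1 it was 3228 for DSS in normal colon, 603 for DSS in tumours and 1617 for the interaction. Within scan day 2 it was 459, 40, 567, 0, 33 and 355. A scan day held 1 to 3 rats per group, and a lone rat was assumed to vary like the other groups. The DSS normal colon of scan day 1 came from rats 1 and 5 alone, which correlated at 0.970 and may be 1 animal. Without the 3 arrays with raised signal the interaction gave 315. With the squamous list mean as a covariate, DSS in normal colon gave 0 genes. Leaving out 1 rat at a time gave 2600 to 5099, 1095 to 2070, 1187 to 2198, 0 to 3, 322 to 792 and 4128 to 5759.

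Single genes that turned were Pcna in tumours of untreated rats within scan day 1 (-0.17), Hadha in tumours of DSS rats with median centring (0.15), Ppan there within scan day 2 (-0.055), and Tiam1 (-0.28) and Csta (-1.20) with DSS in normal colon under the squamous covariate. Lists whose test turned within scan day 2 were enteric nerve in tumours of untreated rats (median 0.39), and, with DSS in tumours, cytokines (0.20), enteroendocrine (-0.79), proteases (0.51), neutrophil (0.13), regenerative (0.042) and squamous (0.15). In the interaction these were enteric nerve (-0.64), enteroendocrine (-0.59), interferon (0.47), mast cell (-0.51) and smooth muscle (-0.35). Within scan day 1 they were proliferation in tumours of untreated rats (-0.26) and over both treatments (-0.061), and interferon in tumours of DSS rats (-0.134). Scan day 2 held 1 DSS rat and scan day 1 held 1 untreated tumour, so turns that involve these groups rest on 1 rat. With DSS in tumours, absorptive genes (0.168) and interferon (-0.90) turned within lot 2, cytokines within lot 1 (0.0745), and regenerative genes with median centring (0.30). Fatty acid oxidation turned in tumours of DSS rats with median centring (0.49) and with DSS in normal colon in the sample channel alone (-0.102). Signal over background limited the lists: on the array with the fewest, 47.6% of the probes were well above background, so changes among dim genes were measured on few arrays.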

Other observations

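The Paneth cell test was written before its result was seen, while the genes Defa6, RatNP-3b, Itln1 and Kcnn4 were singled out after their values were seen. Lists that the comparisons above leave out also moved between tumour and normal colon of untreated rats. Of 9 MHC class II genes, which present antigen, 6 rose and 3 did not pass, 6 over the list alone, with RT1-Bb at 1.71 ± 0.26 (list adjusted p = 0.000184, and 0.154 with an estimated correlation). Of 15 circadian clock genes, 8 fell and 1 rose, with 9 down and 1 up over the list alone, among them Per2 at -1.54 ± 0.26 (list adjusted p = 0.000154, and 0.0812 with an estimated correlation). Of 18 fatty acid oxidation genes, 5 fell, 6 over the list alone, with Hadh at -1.17 ± 0.17 (0.000836, and 0.216 with an estimated correlation). Of 19 interferon response genes, 6 rose, 7 over the list alone, with the GTPase Gbp2 at 4.15 ± 0.33 (0.00104, and 0.406 with an estimated correlation), and list medians of 0.10 and 1.04 within lots 1 and 2. Proliferation genes gave 3 higher of 24 (0.00218, 0.497 with an estimated correlation, and 0.104 without rat 10). B and plasma cell genes gave 1 higher of 9 (0.0315, 0.216 with an estimated correlation, and 0.117 without rat 8). The T and NK cell, mast cell, endothelial, enteric nerve, adipocyte, smooth muscle, hypoxia, heat shock, hedgehog and BMP, immediate early and prostaglandin lists did not pass there.

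In DSS rats, 20 fibroblast and matrix genes had a median of 0.63 between tumour and normal colon with none past the threshold (adjusted p = 4.55e-05, and 0.560 with an estimated correlation), and medians of 0.19 and 1.35 within lots 1 and 2. Of 12 smooth muscle genes, 2 rose, 6 over the list alone (0.000906, and 0.282 with an estimated correlation). With DSS in normal colon, 2 of 14 heat shock genes rose, with 6 up and 2 down over the list alone (0.00738, and 0.208 with an estimated correlation). With DSS in tumours, hypoxia and glycolysis genes had a median of -0.29 with none past the threshold (0.000518, 0.594 with an estimated correlation, and 0.0615 without rat 4).

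Defa6 and Mmp7, both made by Paneth cells elsewhere in the gut, rose in tumours of untreated rats and in normal colon of DSS rats, Defa6 by 4.70 and 4.25. A hypothesis was that Paneth cell genes rise as a group. A list of 18 such genes without those seen before had 10 measured, 3 of them in another list. It had medians of -0.188 and -0.09 in these comparisons, with camera p-values of 0.986 and 0.570. The bound set beforehand against the hypothesis, a median under 0.25 in both, was met, but members went both ways (3 higher and 3 lower in tumours, SD 1.47), so the median decides nothing. The defensin RatNP-3b, also a neutrophil peptide, rose by 3.28 ± 0.36 and 2.81 ± 0.36, so it does not by itself point to Paneth cells. The neutrophil list passed in both comparisons in camera, but not with an estimated correlation. Itln1 fell in both (-1.02 and -1.22), and Kcnn4 fell in tumours (-1.72).

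The normal colon samples of DSS rats 1 and 5 correlated across genes at 0.970, the highest of any pair of arrays, which is higher than the second arrays of the same sample (0.813 to 0.968). Whether both came from 1 RNA or 1 animal is not known here; the group would then hold 4 rats, and its spread would be understated. The squamous list mean was 2.14 in rat 1 and 2.57 in rat 5, the widest gap between them of any list. By contrast, the macrophage mean was 0.162 and 0.165, and the absorptive mean -0.574 and -0.636. DSS in normal colon gave 1366 genes without rat 1 and 1248 without rat 5, against 1905 with both. The lowest correlation of any pair of arrays was 0.303.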
